A study of Rattus norvegicus with 27 samples.

How the data were processed

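Genomic DNA from the renal outer medulla of individual Dahl salt-sensitive (SS) rats was profiled by reduced representation bisulfite sequencing (RRBS). In this assay the restriction enzyme MspI and a size selection enrich CpG-rich fragments. Bisulfite then converts unmethylated cytosines, so that a C read at a CpG counts as methylated and a T as unmethylated. The 27 libraries form 7 groups, and per the labels each library is 1 rat, so the spread between libraries includes the spread between animals.

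The deposited data are 2 tables of counts. Each gives, per rat, the number of C and of T reads at each CpG position, per the file headers, and a missing value was read as a position without reads. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.2.5 and the genome build was rn5. The aligner and the methylation caller are not given in the sources used here. No listed position has a neighbouring row 1 bp away, so each CpG has 1 row and the strands were treated as merged. Whether PCR duplicates were removed is not given in the sources used here; the reads carry no molecular identifiers that are described in the labels, and binomial intervals below cover counting error only. The first table holds the 15 libraries of the MCW and CRL colonies over 2852395 positions, and the second the 12 libraries of the GapmeR experiment over 5477824 positions. All columns matched a sample by the animal number in the labels. The letters RP stand on a column of MCW_LS and a column of CRL_LS. For MCW_LS the title puts them on replicate 1 and the description and column name on replicate 2, so the column name was followed. The tables were tested separately, because they differ in depth and in the sites they hold, and no level was compared by a test across them.

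The methylation level of a rat at a site is its methylated count as a percentage of all its counts there. Sites with at least 10 reads in every library of the table were kept, which left 484749 sites in the first table and 1219703 in the second (common sites). For each comparison, sites with a pooled level from 5 to 95% over the compared libraries were tested. The model was a quasi-binomial logistic regression on the counts with 1 value per rat. The Pearson dispersion of each site was moderated with squeezeVar of limma 3.58.1 (trend on log mean coverage) and held at 1 or more. The group term was tested with a two-sided F test on the deviance, and p-values were adjusted by the Benjamini-Hochberg method over the sites tested. A call is an adjusted p below 0.05. The same model was run on counts summed over fixed bins of 500 bp with at least 3 common sites. The difference of salt effects between the colonies was tested as an interaction term in the same model. Differences between groups are differences of the mean levels of the rats, in percentage points, and SE is the standard error of that difference. Computations used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and R 4.3.3. Figures were drawn with matplotlib 3.10.9.

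The test was checked on simulated counts with the depth and levels of the real sites, the moderated dispersion of each site and 200 changed items. For MCW SS on high against low salt the test recovered 0% of sites changed by 10 points, 3% at 20 points and 32% at 30 points. False calls at these sizes were 2, 9 and 16. At 10 and 20 points they outnumbered the recovered sites, and at 30 points they made up more than 0.05 of all calls. An adjusted p below 0.05 therefore did not hold its error rate at any of these sizes. The calls at single sites below carry that limit. On bins of the same comparison the test recovered 0%, 59.5% and 95.5%, with up to 21 false calls. For HS_SCR against 0.4% salt, site recoveries were 0%, 16% and 64.5% and bin recoveries 7%, 78% and 99.5%, with up to 25 false calls at sites and 16 at bins. At 30 points the false calls were more than 0.05 of all calls at sites and bins of both comparisons. Of the unchanged items, 5.04 to 6.25% had an unadjusted p below 0.05, which is the background for later counts at that p. A criterion set before this check, that most single sites changed by 30 points be recovered for MCW SS on high against low salt, was not met. After that result was seen, the criterion was moved to bins changed by 30 points for HS_SCR against 0.4% salt, and the simulated dispersion was changed from 1 value for all items to that of each item.

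Mean methylation per rat is the unweighted mean level over common sites, compared by an exact two-sided permutation test of the group means with adjustment over the 7 comparisons. Classes of sites by their mean level over all libraries of a table (under 20%, 20 to 80%, over 80%) were chosen after the data were examined, and so was the test of a mean salt effect over both colonies. The other comparisons, their tests, the thresholds and the rule for named regions were fixed before the data were examined. Per comparison the rule names up to 15 bins per direction that pass the test with at least a 10 point difference and groups that do not overlap. Where fewer than 5 qualify, it names the 5 bins with the smallest p in each direction, as values without a verb of change. It also names at most 3 single sites per direction. No reference genome or gene annotation of rn5 was used here, so regions are given by rn5 coordinates (1-based). The gene lists chosen beforehand (sodium transport, blood pressure hormones and receptors, oxidative stress, immune cells and inflammation, fibrosis and matrix, DNA methylation machinery, imprinted genes, homeobox genes and markers of kidney cell types) were not tested.

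Alternatives were a coverage minimum of 5 or 20 reads, 10 reads in at least 3 libraries per group, no filter on the pooled level, 1000 bp bins, 5 sites per bin and 1 dispersion for all groups of a table. Further alternatives were edgeR 4.0.16 on the methylated and unmethylated counts and limma on log2 ratios of those counts with a pseudocount of 1. Blocks for the replicate number or the range of animal numbers were used too. The libraries marked RP were omitted, and so was each library in turn. A further omission took out sites under 10% in every rat of one colony and over 40% in every rat of the other. Other splits of the same libraries into groups of the same sizes were tested for every count of calls, after those counts had been seen. Other additions after the data were examined were a correlation over all sites for the reversal in HS_DT, the alternatives for sites of 20 to 80% in both colonies, the omission of each library in turn for the same class in HS_SCR against PRE_LS, and the omission of positions whose counts in all libraries equal those of a position more than 1 kb away, which is how reads counted at several near-identical places would look.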

Results

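DNA methylation was measured by RRBS in the renal outer medulla, a part of the kidney that holds the medullary thick ascending limbs. The animals were Dahl SS rats, an inbred strain whose blood pressure rises on a high-salt diet. The first experiment held rats of a colony named MCW and of a colony named CRL. MCW rats were kept on the purified diet AIN-76A with 0.4% NaCl (MCW_LS, n = 3) or on AIN-76A with 4% NaCl for 14 days from 6 weeks of age (MCW_HS, n = 4). CRL rats received the same 4% NaCl diet (CRL_HS, n = 4), but their low-salt group was kept on another, non-purified diet, 5L2F, with 0.75% NaCl (CRL_LS, n = 4). The second experiment used MCW SS rats. HS_SCR rats (n = 4) received 4 mg/kg of a scrambled GapmeR, an antisense oligonucleotide, into the kidney and 4% NaCl for 7 days. HS_DT rats (n = 4) received GapmeRs against Dnmt3a, a de novo DNA methyltransferase, and Tet3, an enzyme that oxidises methylcytosine, at 2 mg/kg each. Their time on 4% NaCl is given as 7 without a unit. PRE_LS rats (n = 4) had the same surgery and were sampled on 0.4% NaCl before GapmeR and high salt would have begun. The tables hold no expression values, so the levels of Dnmt3a and Tet3 were not measured here.

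The libraries of the first experiment held 35040331 to 95102303 CpG read counts and those of the second 174400859 to 257658964. The median depth at common sites was 24 to 66 reads per library in the first table and 66 to 98 reads in the second. The deepest library of the first table was MCW_LS replicate 2. Sites in CpG-dense bins had low methylation in both tables. Sites in bins with 1 to 2 common sites had a mean level of 52.4% ± 0.327 (SD over 15 rats) in the first table, and sites in bins with 20 or more had 2.29% ± 0.220. In the second table these levels were 46.1% ± 0.349 and 3.07% ± 0.0722 (SD over 12 rats), but the highest level there, 52.6% ± 0.330, was in bins with 3 to 9 common sites. The X chromosome stood above the other chromosomes, at 40.2% ± 0.275 in the first table and 46.0% ± 0.213 in the second. Of the common sites of the first table, 66.8% had a mean level under 20%, 18.5% lay from 20 to 80% and 14.7% above 80%.

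No comparison of mean methylation over all common sites passed the exact permutation test. Mean methylation was 23.3% ± 0.170 in MCW_LS (SD, n = 3), 23.6% ± 0.265 in MCW_HS, 23.3% ± 0.128 in CRL_LS and 23.5% ± 0.150 in CRL_HS (n = 4 each). It was 29.7% ± 0.0930 in PRE_LS, 29.7% ± 0.3496 in HS_SCR and 29.7% ± 0.0543 in HS_DT (n = 4 each). HS_SCR replicate 4 stood at 29.2% and the other HS_SCR rats at 29.8% or more. With each library left out in turn, HS_SCR minus PRE_LS ranged from -0.0670 to 0.186 points and HS_DT minus HS_SCR from -0.181 to 0.0719. High salt minus low salt was 0.236 points in MCW rats (SE 0.165, higher in 10 of 12 pairs of rats) and 0.168 points in CRL rats (SE 0.0987, higher in 13 of 16 pairs). Weighted by reads these were 0.739 and 0.850 points, the colony difference on high salt went from 0.0628 to -0.421, HS_SCR minus PRE_LS from 0.0131 to 1.75 and HS_DT minus HS_SCR from -0.00819 to -1.41, and none passed the exact permutation test. The adjusted p of the exact permutation test was 1 for each of the 7 comparisons. The design allows an unadjusted p of 0.0571 for 3 against 4 rats and 0.0286 for 4 against 4.

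**Figure D1:**
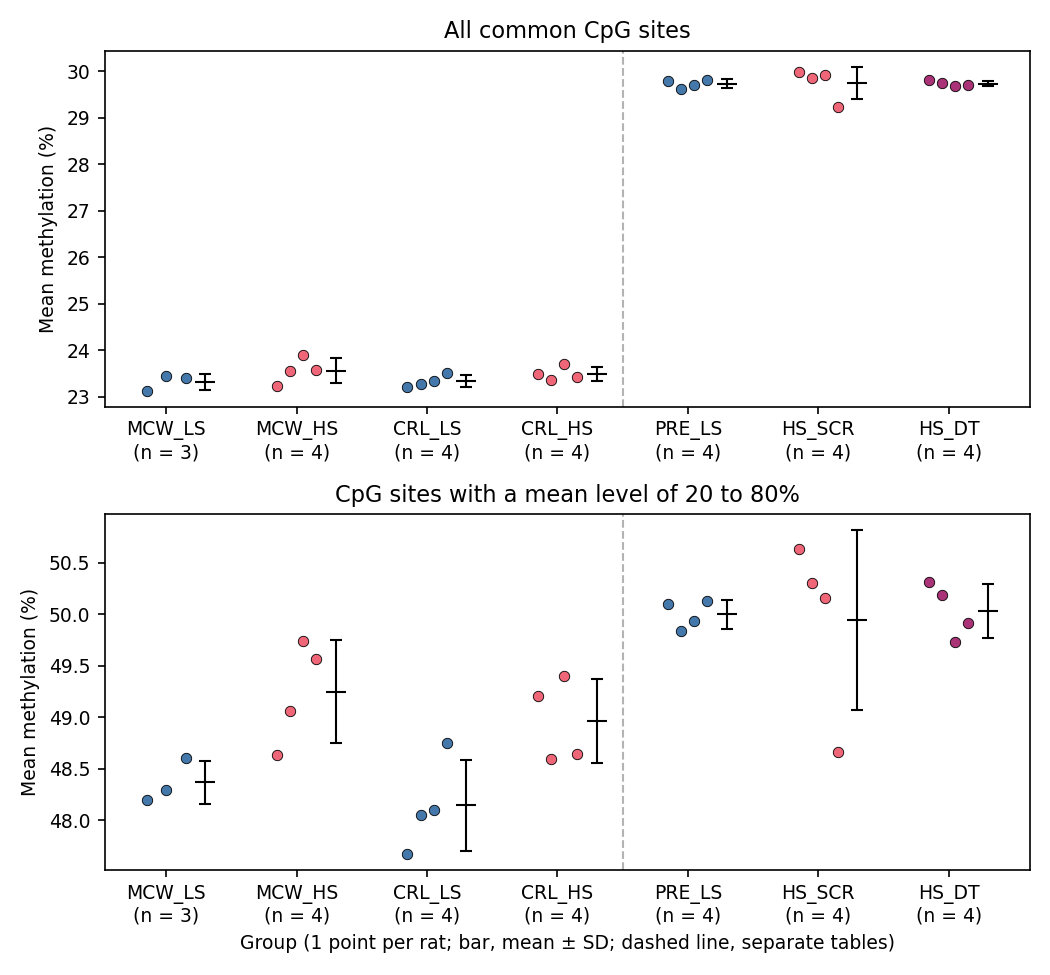
Mean methylation (%) of each rat over all common CpG sites (top) and over sites with a mean level of 20 to 80% (bottom), by group, with the group mean ± SD. The axes do not start at 0. Rats of one group lie within 1 percentage point of each other over all sites, and over sites of 20 to 80% the 4 MCW_HS rats lie between 48.6 and 49.7%, each above the 3 MCW_LS rats.

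In sites of intermediate methylation, the mean level was higher on high salt in the mean over both colonies. Over the 89565 common sites of 20 to 80%, MCW_HS rats had 49.2% ± 0.499 (SD, n = 4) and MCW_LS rats 48.4% ± 0.213 (n = 3), with MCW_HS higher in 12 of 12 pairs of rats. CRL_HS rats had 49.0% ± 0.404 and CRL_LS rats 48.1% ± 0.446 (n = 4 each), with CRL_HS higher in 14 of 16 pairs. The mean salt difference over both colonies was 0.851 points (exact permutation of diets within colony, p = 0.00327, adjusted p = 0.0131 over 4 classes). Within a single colony the difference did not pass the exact permutation test (adjusted p = 0.9 in each, over the 21 comparisons of 3 classes). In the second experiment, where HS_SCR rats also received the scrambled GapmeR and high salt lasted another time, HS_SCR minus PRE_LS was -0.0597 points with an SE of 0.442, although HS_SCR was higher in 12 of 16 pairs. That sign rests on HS_SCR replicate 4, without which the difference was 0.365 points with HS_SCR higher in 12 of 12 pairs (exact permutation p = 0.0571, the smallest this size allows). Sites under 20% and over 80% differed by 0.0388 and 0.127 points over both colonies (adjusted p = 0.637 and 0.607, exact permutation). All common sites differed by 0.202 points (p = 0.0596, adjusted p = 0.119, exact permutation). Whether the salt difference differs between classes was not tested. The classes, this test and that omission were chosen after the data were examined, and in CRL rats the low- and high-salt diets also differ in their base.

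The salt response of MCW rats was the first question of the study at single regions. No 500 bp bin passed the test among 28188 (limma-moderated quasi-binomial model, smallest adjusted p = 0.576). At an unadjusted p below 0.05 there were 1755 bins (6.23%), and limma on log ratios also called 0. The groups did not overlap in 1720 bins (6.10%), and chance gives 5.71% for 3 against 4 rats. On chromosome 11, 33583501 to 33584000 (6 CpGs), methylation was 42.3% ± 1.40 in MCW_HS (SD, n = 4) and 24.9% ± 2.98 in MCW_LS (n = 3), with 198 to 342 reads per rat. On chromosome 15, 107591501 to 107592000 (13 CpGs), it was 25.3% ± 1.44 and 13.1% ± 2.45. The bin on chromosome 13 from 109987001 to 109987500 had 39.1% ± 6.02 and 17.2% ± 3.57. Lower values on high salt stood on chromosome 14, 15629501 to 15630000, with 49.995% ± 1.42 against 62.5% ± 4.13. A second bin at 15634001 has the same values and cannot be separated from it. On chromosome 10, 10883001 to 10883500, the levels were 65.4% ± 4.93 against 84.7% ± 6.31, and on chromosome 17, 26097001 to 26097500, they were 15.6% ± 2.34 against 34.3% ± 6.58. For the 10 named bins the adjusted p was 0.576 or 0.630, and 5 of 9 distinct bins had the same sign in CRL rats, where named bins within 2 points of each other in every rat count once.

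**Figure D2:**
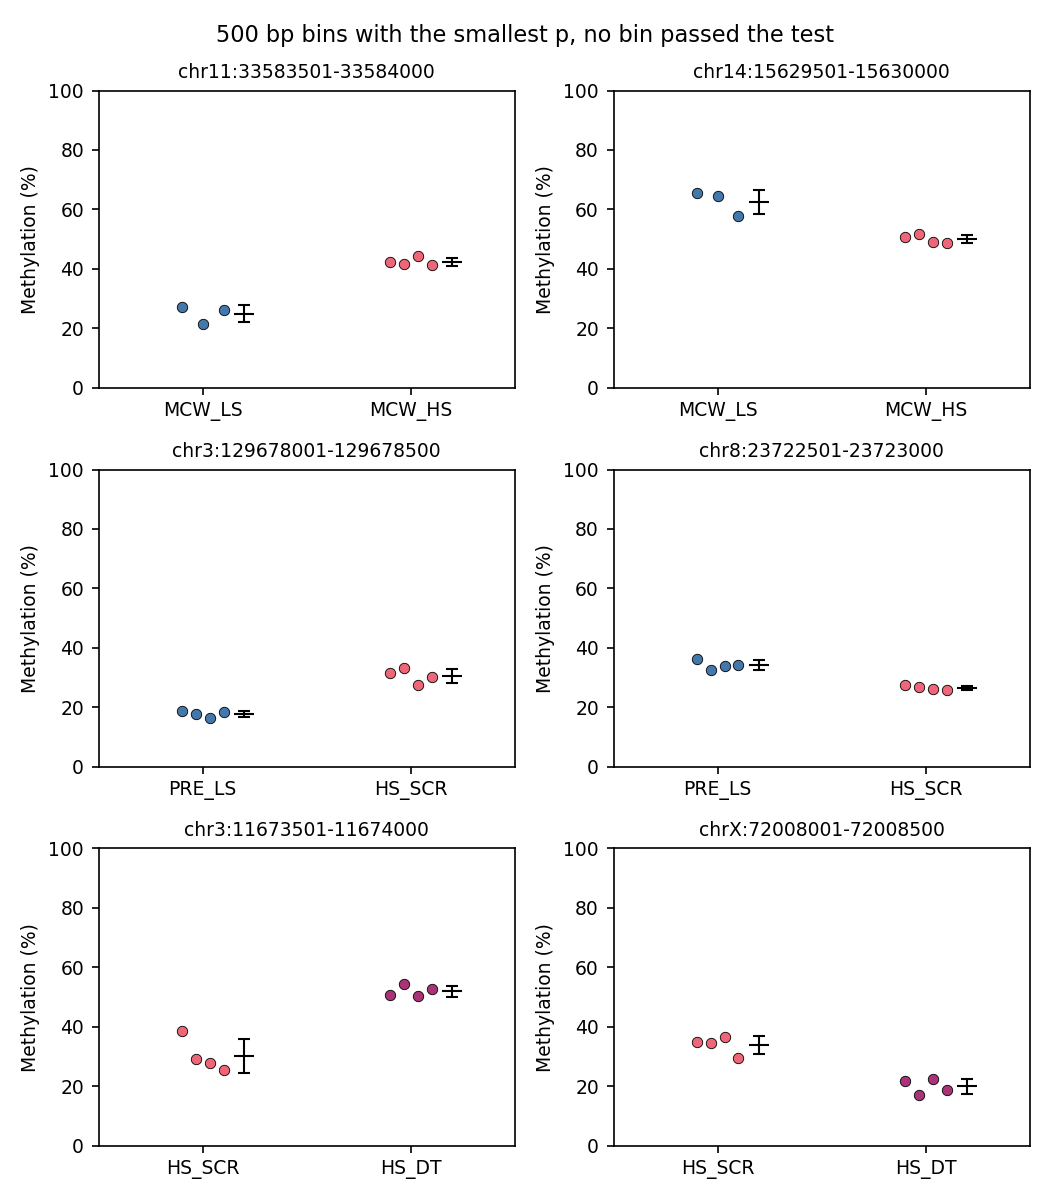
Methylation (%) of each rat in 6 of the 500 bp bins with the smallest p, for MCW_HS against MCW_LS (top), HS_SCR against PRE_LS (middle) and HS_DT against HS_SCR (bottom), with the group mean ± SD. These bins were picked for their small p, so their groups lie apart in each panel, and none of them passed the adjusted test.

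At single CpGs, 147 of 165091 sites passed the test between MCW_HS and MCW_LS, 26 higher and 121 lower on high salt. The groups did not overlap at 70 of these 147 sites. The site at position 12873723 of chromosome 15 had the smallest p. Its level was 12.3% ± 4.96 in MCW_HS (SD, n = 4) and 55.5% ± 18.5 in MCW_LS (n = 3), with 42 to 185 reads per rat (adjusted p = 0.00508). The site with the smallest p among those higher on high salt lies on chromosome 6 at 39272925. It had 57.1% ± 11.4 against 27.9% ± 16.0 (adjusted p = 0.00525) at 626 to 3304 reads per rat. It lies in a cluster of 12 called sites from 39262101 to 39274606. The next sites in this direction had nearly the same levels and reads. At 46861726 of chromosome 14 they were 56.2 against 27.7% (647 to 3280 reads). At 13558437 of chromosome 1 they were 55.7 against 27.6% (652 to 3314 reads). An unadjusted p below 0.05 was found at 10452 sites (6.33%), and edgeR and limma called 0. No site passed without MCW_LS replicate 2, and omission of MCW_HS replicates 2, 3 or 4 left 32, 41 and 32, while omission of MCW_LS replicates 1 or 3 gave 268 and 352. The lean to lower calls depends on MCW_LS replicate 3, without which 162 were higher and 190 lower. The count was 90 at a minimum of 20 reads, 45 with a block for the range of animal numbers and 0 without a filter on the pooled level. Of the 35 splits of these 7 libraries 4 gave as many calls, so the count does not set this comparison apart from other groupings.

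In CRL rats, where the diets also differ in base, no bin passed among 28039 in the same model. There were 1661 (5.92%) at an unadjusted p below 0.05 and 0 by limma on log ratios. Methylation on chromosome 6, 137744501 to 137745000 (6 CpGs), was 48.4% ± 4.19 in CRL_HS and 28.5% ± 6.10 in CRL_LS (SD, n = 4 each). On chromosome 19, 23752501 to 23753000 (3 CpGs), it was 64.9% ± 2.91 and 44.1% ± 3.45. Lower values on high salt were 35.2% ± 2.81 against 51.5% ± 5.84 on chromosome 2, 45212501 to 45213000, where MCW rats differed by 18.9 points the other way. They were 25.2% ± 8.45 against 49.98% ± 8.56 on chromosome 2, 270205001 to 270205500. The adjusted p of the 10 named bins was 0.626, and 4 of 9 distinct bins had the same sign in MCW rats. At single sites 24 of 163017 passed, 24 higher and 0 lower on high salt, the first of them at 13561020 of chromosome 1 with 56.2% ± 16.3 against 29.1% ± 9.44 (adjusted p = 0.0383). The groups did not overlap at 15 of the 24 sites. At 13561020 they did overlap (lowest CRL_HS rat 40%, highest CRL_LS rat 41.7%), at 20 to 420 reads per rat. That site lies in a cluster of 25 called sites of the first table, from 13498484 to 13564781, and the median depth of the 24 sites was 28.1 times that of their library. An unadjusted p below 0.05 was found at 12075 sites (7.41%), and edgeR and limma called 0. No site passed without CRL_HS replicate 3 or CRL_LS replicates 1 or 2, 1 without CRL_LS replicate 3, and 41, 56 and 323 without CRL_HS replicates 1, 2 and 4. The count was 0 at a minimum of 20 reads, without a filter on the pooled level and with 1 dispersion for all groups. Of the 35 splits, 4 gave as many calls.

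Whether the colonies respond differently was tested directly as an interaction. The salt effect differed at 149 of 164329 sites, 9 with a higher and 140 with a lower effect in MCW rats. The site with the smallest p was 13561020 of chromosome 1, named above for CRL salt from the same CRL rats and in the same cluster. Its salt difference was -26.1 points in MCW and 27.1 points in CRL rats (adjusted p = 2.72e-04). Limma called 0, and 9697 sites (5.90%) had an unadjusted p below 0.05. The count was 6 without MCW_LS replicate 2 and 7 without CRL_HS replicate 3. It was 245 and 227 without MCW_LS replicates 1 and 3, 72 without MCW_HS replicate 3, and 69 and 99 without CRL_LS replicates 2 and 3, and 85 at a minimum of 20 reads. Among 100 splits with diets permuted within colony, the real one included, 6 gave as many calls.

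The colonies were compared on each diet. No bin passed among 27982 on low salt or 28242 on high salt, and limma on log ratios called 0. At an unadjusted p below 0.05 there were 1573 (5.62%) and 1681 (5.95%). The exception was 135 bins that passed on low salt without MCW_LS replicate 3. On low salt, where the colonies ate different diets, methylation on chromosome 15, 2359501 to 2360000 (8 CpGs), was 39.0% ± 3.26 in MCW_LS (SD, n = 3) and 23.9% ± 2.07 in CRL_LS (n = 4). On chromosome 16, 60043501 to 60044000, it was 46.1% ± 0.117 against 61.3% ± 3.96, and on high salt the difference there was -11.6 points. On high salt, on the same diet, chromosome 4, 194885001 to 194885500, had 75.3% ± 1.57 in MCW_HS and 57.7% ± 4.93 in CRL_HS (n = 4 each). Chromosome 10, 73188501 to 73189000, had 3.82% ± 1.04 against 16.9% ± 4.95. Of the 10 distinct bins named on low salt 9 had the same sign on high salt. Of the 8 distinct bins named on high salt 4 had it on low salt, since on chromosome 3 the bins at 8559501 and 8588501 hold equal values and the bin at 8536001 lies within 2 points of them in every rat.

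At single sites the colonies differed at 28 of 162736 on low salt (8 higher and 20 lower in MCW) and at 107 of 165046 on high salt (5 higher and 102 lower). The groups did not overlap at 16 and 61 of these sites. The site at 58903759 of chromosome 16 was lower in MCW on low salt. It had 0 methylated reads in each of the 7 MCW rats, at 23 to 50 reads, where 3 counts of the total allow a level of up to 13.0% in the rat with the fewest and the 95% Wilson interval reaches 14.3%. It stood at 52.0% ± 10.3 in the 8 CRL rats (SD, range 33.3 to 64.7%). On high salt the site with the smallest p was 13561020 of chromosome 1, in the cluster named above, with 13.7% ± 7.24 in MCW_HS and 56.2% ± 16.3 in CRL_HS (adjusted p = 1.43e-05). The same CRL_HS rats stand in the tests that named it above. Of the 107 sites, 55 were also called for MCW salt and 13 for CRL salt, tests that share the MCW_HS or CRL_HS rats. On low salt edgeR called 0 sites and limma 1, and the count was 2 without MCW_LS replicate 2, 219 without replicate 1, where the direction turned to 152 higher and 67 lower, and 5157 without replicate 3 (458 higher and 4699 lower), and 5, 13, 18 and 10 without CRL_LS replicates 1 to 4. It was 81 at a minimum of 20 reads, 45 without positions of equal counts (chosen after the data were seen), 13 with 10 reads in at least 3 libraries per group, 7 with 1 dispersion for all groups, 2 without the RP libraries and 1 without a filter on the pooled level. On high salt edgeR called 0 and limma 1, and the count was 8 without CRL_HS replicate 3, 193 without CRL_HS replicate 4, 55 without MCW_HS replicate 4, 57 with 1 dispersion for all groups and 14 without a filter on the pooled level. Splits as large numbered 5 and 2 of 35.

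**Figure D3:**
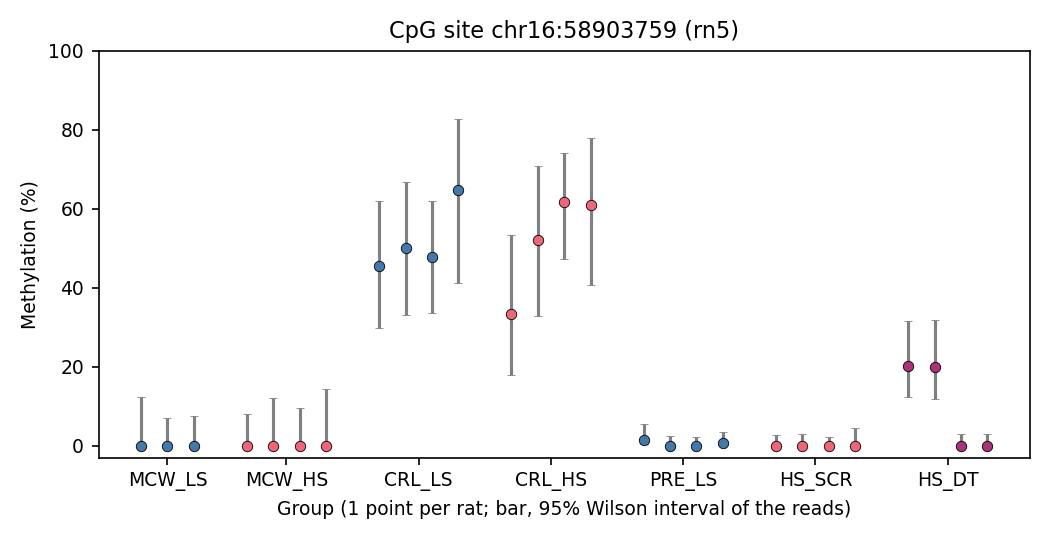
Methylation (%) at the CpG at 58903759 of chromosome 16 (rn5) in each rat of all 7 groups, with 95% Wilson intervals of the reads. The 7 MCW rats of the first experiment are at 0%, and the 8 CRL rats lie between 33.3 and 64.7%.

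In the GapmeR experiment, the first comparison asks how 7 days of high salt with the scrambled GapmeR differ from the state before. No bin passed among 96299 (4595 or 4.77% at an unadjusted p below 0.05, limma 0) and no site among 526526 (28637 or 5.44%, edgeR 0, limma 0). Adjacent bins on chromosome 3 had the smallest p for higher levels. In 129678001 to 129678500 (3 CpGs) methylation was 30.6% ± 2.44 in HS_SCR and 17.9% ± 1.00 in PRE_LS (SD, n = 4 each), and in 129677501 to 129678000 (21 CpGs) it was 36.0% ± 1.75 and 26.7% ± 1.67 (adjusted p = 0.772 for both). On chromosome 10, 104275501 to 104276000, the levels were 39.4% ± 4.29 and 59.1% ± 3.88. On chromosome 8, 23722501 to 23723000, they were 26.5% ± 0.767 and 34.2% ± 1.58, with a second bin at 24232001 holding the same values. Leaving out HS_SCR replicate 4 or PRE_LS replicate 3 gave 6 sites each, and HS_SCR replicate 2 gave 1. Simulated differences of 20 points, in bins of intermediate level, were recovered in 78% of cases at this depth, and those of 10 points in 7%. There 200 bins were changed at once, which eases the adjusted threshold, so fewer would be recovered where few bins differ. The bin on chromosome 10 above, with a difference of -19.7 points, had an adjusted p of 0.772 in the quasi-binomial model.

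The second comparison asks how the GapmeRs against Dnmt3a and Tet3 differ from the scrambled one under high salt. No bin passed among 96356 (4248 or 4.41% at an unadjusted p below 0.05, limma 0) and no site among 527815 (25962 or 4.92%, edgeR 0, limma 0). Both shares lie below those of unchanged items in the simulation. Leaving out HS_DT replicate 4 or HS_SCR replicates 2 or 3 gave 1, 1 and 2 sites. On chromosome 3, 11673501 to 11674000 (8 CpGs), methylation was 52.0% ± 1.84 in HS_DT and 30.2% ± 5.73 in HS_SCR (SD, n = 4 each, adjusted p = 0.430). PRE_LS rats stood at 46.9% ± 15.8 in that bin. On chromosome 17, 25209501 to 25210000, the levels were 67.8% ± 4.75 and 48.8% ± 2.95. On the X chromosome, 72008001 to 72008500 (9 CpGs), they were 19.99% ± 2.57 and 33.8% ± 3.12, and on chromosome 6, 144002001 to 144002500, they were 34.1% ± 2.86 and 50.6% ± 2.90.

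HS_DT rats were also set against the state before treatment. Most HS_DT rats have animal numbers in a lower range than all PRE_LS rats, so treatment and range can hardly be told apart here. No bin passed among 96261 (5018 or 5.21% at an unadjusted p below 0.05, limma 0). No site passed among 525381 (29462 or 5.61%, edgeR 0, limma 0), with 1 site without PRE_LS replicate 3. On chromosome 10, 71998501 to 71999000 (11 CpGs), methylation was 12.7% ± 1.43 in HS_DT and 5.18% ± 1.12 in PRE_LS (SD, n = 4 each, adjusted p = 0.381). On chromosome 15, 54879501 to 54880000 (7 CpGs), it was 32.7% ± 4.48 and 51.3% ± 2.00, and HS_SCR rats stood at 35.7% ± 8.52. The bin at 129678001 on chromosome 3, named above, had 28.5% ± 2.68 in HS_DT, and both differences share the PRE_LS rats.

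High salt was set against low salt in MCW rats in both experiments, which share no rat, and the differences showed no detectable correlation across sites. HS_SCR minus PRE_LS holds the scrambled GapmeR and the time after surgery as well as salt. HS_SCR replicates 1 and 2 also have animal numbers in a lower range than the PRE_LS rats. The correlation of MCW_HS minus MCW_LS with HS_SCR minus PRE_LS was -0.00147 over 145253 sites (p = 1 over 70 regroupings of the second table, an exact permutation). Sites are not independent replicates. Of the 134 sites called in the first experiment and tested in both, 9.70% had the same sign in the second (exact permutation p = 0.0571, other regroupings 7.46 to 92.5%). The reverse could not be computed over called sites because none passed in the second table. Of the 9 distinct bins named for MCW salt, 3 had the same sign there, and of the 4 bins named for HS_SCR against PRE_LS that were measured in the first table, 2 had the same sign for MCW salt.

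Whether HS_DT reversed the HS_SCR response was tested with the HS_SCR rats split, since they stand in both differences. Sites were called with 2 HS_SCR rats against PRE_LS, and HS_DT was set against the other 2. Over the 6 splits 5354 sites were called, 5345 of them with HS_SCR replicates 1 and 2. These 2 rats and most HS_DT rats have animal numbers in a lower range than PRE_LS and the other 2 HS_SCR rats. A difference between ranges alone would give both differences the same sign. That split therefore cannot tell a reversal, or its absence, from the range, and the drawn regroupings below do not keep the ranges. The share of opposite sign was 6.39%, against a median of 15.7% and a range of 0 to 100% in the 22 drawn regroupings that had calls (31 groupings of the 12 libraries, the real one included, permutation p = 0.957). The median difference in the direction of the call was 3.44 points (permutation p = 0.696). Both values rest on the split with 5345 calls, where 6.30% had the opposite sign. The other splits with calls gave 50% of 2 sites, 75% of 4 and 33.3% of 3, with medians of -5.77, -17.4 and 0.208 points. No bin was called in these splits. With all HS_SCR rats in both differences, the correlation over sites was -0.514, and with the rats split its mean was 0.0241 (permutation p = 0.146), a measure chosen after the data were examined.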

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

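Tests in this part that were chosen only after the result was seen are the splits for counts of calls, the clusters of called sites, the share of equal-count positions among called sites, pooled and per comparison, the depth of each library at called sites, the bisulfite conversion test, the test of the diet base and the alternatives without equal-count positions or RP libraries for the class of 20 to 80%.

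The salt effect differed between MCW and CRL rats at 149 single CpG sites by the test of the interaction itself. Chance cannot be excluded for this count, since 6 of 100 splits of the diets within colony, the real one included, gave as many calls, with 5635 in the highest of the others. The count was 6 without MCW_LS replicate 2 and 7 without CRL_HS replicate 3.

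Chance cannot be excluded for the counts of called sites in single comparisons either. For MCW salt 4 of 35 splits gave as many (real 147, highest other 6373) and for CRL salt 4 (24, 194). For the colonies the number was 5 on low salt (28, 98) and 2 on high salt (107, 217). For sites in the GapmeR experiment and for bins in each of the 7 comparisons the real count was 0, which makes 35 of 35 splits as large by construction, so nothing about chance follows. The highest other splits gave 477 sites for HS_SCR against PRE_LS, 825 for HS_DT against HS_SCR and 1 for HS_DT against PRE_LS. For bins they gave 196 for MCW salt, 1 for HS_DT against PRE_LS and 0 for the rest. The split with 6373 sites set MCW_HS replicates 1 and 4 with MCW_LS replicates 1 and 2 against the other MCW rats, and the second highest gave 6247. Such counts may reflect a structure of the samples or a count that swings with single libraries. The 2 were not separated, and no source was identified.

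Of the 224 sites called in any of the 4 comparisons of the first table, 81 fall in 4 clusters, on chromosome 1 (13498484 to 13564781, 25 sites), chromosome 14 (46816649 to 46864012, 27), chromosome 5 (95169606 to 95177655, 17) and chromosome 6 (39262101 to 39274606, 12). Sites at 13554770, 46816649 and 95169606 of chromosomes 1, 14 and 5 have identical salt differences of -34.2 points in MCW and 34.2 points in CRL rats. For CRL salt, 13559018 of chromosome 1 and 46823576 of chromosome 14 share their levels as well. Such positions cannot be counted as separate calls. For MCW salt, 39272925 of chromosome 6, 46861726 of chromosome 14 and 13558437 of chromosome 1 had nearly equal levels and reads, so they may not be separate calls either. The median depth of called sites was 3.38 times that of their library (28.1 for CRL salt), against 0.928 for tested sites. Reads counted at several near-identical places could produce this, and identical values are how such reads would look. How many of the other calls this covers stays open. Positions with counts equal to those of a distant position made up 12.9% of called sites (95% Wilson interval 9.17 to 17.97%) and 8.90% of tested sites, a ratio of 1.46. The ratio was 3.70 for CRL salt (8 of 24 calls, interval 1.99 to 5.92) and 2.19 for the colonies on high salt (1.48 to 3.15). For MCW salt it was 1.29 (0.822 to 1.99). For the colonies on low salt it was 0 (0 of 28, upper bound 1.34), beside a median depth of 5.43 times that of the library. Copies with nearly equal counts are not found by this measure, and the intervals treat positions as independent, which copies are not. For MCW salt 0 sites passed without MCW_LS replicate 2, which is both the deepest library and one marked RP, and at the 147 called sites the median depth was 5.26 times its own median in that library and 6.70 times in CRL_HS replicate 3, against 2.05 to 3.24 in the others, so a deep library is a candidate source, but its depth, the mark and a read excess at these sites were not separated. Diet and colony stay open.

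Sites of 20 to 80% were higher on high salt by 0.851 points over both colonies, a pattern found and tested on the same rats. Incomplete bisulfite conversion would raise sites under 20% too, and they differed by 0.0388 points (SE 0.0752), while depth predicts 0.00697 points (SE 0.0313), so both argue against these as the whole cause. The difference was 0.846 points without equal-count positions and 0.827 points without the RP libraries (exact permutation p = 0.0152). Neither positions with exactly equal counts nor these libraries account for it. Copies with nearly equal counts were not removed, so reads counted at several near-identical places stay open to that extent. MCW rats, whose diets share their base, differed by 0.883 points (SE 0.278, 12 of 12 pairs). That value is part of the mean of 0.851 points, and alone it did not pass the exact permutation test (p = 0.0571, adjusted p = 0.9). It argues only weakly against the diet base of CRL rats as the whole cause. Cell composition of the tissue and an unrecorded library batch stay open and were not tested, as does diet itself.

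A gap test found 6 of 148 groups with a rat far from the others, and chance gives about 1 in 20. Over sites under 20%, a PRE_LS rat was lowest at 1.65%, with the highest of its group at 1.83%. In the bin at 23752501 of chromosome 19 a CRL_HS rat was lowest at 60.6%. In the bin at 35724001 of chromosome 19 a CRL_LS rat was lowest at 31.1%. In the bin at 114353501 of chromosome 13 a CRL_HS rat was highest at 88.4%. In the bin at 44295001 of chromosome 8 a HS_SCR rat was highest at 81.3%. In the bin at 198327001 of chromosome 4 a PRE_LS rat was highest at 33.5%.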

How the results depend on the processing

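Counts of called bins stayed at 0 under 81 of 82 alternatives, the exception being 135 for the colonies on low salt without MCW_LS replicate 3. Counts of called sites stayed within 1.5 times under 29 of 89 alternatives of results with calls, and at 0 under 44 of 54 of results with none. The alternative without equal-count positions and the omissions for sites of 20 to 80% were chosen after the data were seen. Counts below are for MCW salt, CRL salt, the colonies on low salt and the colonies on high salt, and the cause was not tested. edgeR gave 0, 0, 0 and 0, and limma 0, 0, 1 and 1, with 0 for the interaction. Without a filter on the pooled level they were 0, 0, 1 and 14. At a minimum of 20 reads, with fewer sites tested, MCW salt gave 90, CRL salt 0, the colonies on low salt 81 and the interaction 85. With 1 dispersion for all groups CRL salt gave 0, the colonies 7 and 57. Without the libraries marked RP MCW salt gave 0, CRL salt 1 and the colonies on low salt 2. With 10 reads in at least 3 libraries per group the colonies on low salt gave 13, and without equal-count positions 45. A block for the range of animal numbers left 45 for MCW salt, and the shared range alone gave 3 for HS_SCR against PRE_LS.

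The replicate block gave 0, 0, 0 and 7, then 2 for HS_SCR against PRE_LS, 1 for HS_DT against HS_SCR and 111 for the interaction. Same-numbered rats did not deviate together (correlations from -0.0874 to 0.0626, none over 0.1), so the numbers do not pair them. The mean methylation difference of the colonies on low salt was 0.0543 points under the block, which has no partner for CRL_LS replicate 4, and omission of that rat alone gave the same value, so the omission turned the sign. An alternative without sites under 10% in every rat of one colony and over 40% in every rat of the other removed 0 sites and is not counted above. The site at 58903759 of chromosome 16 stayed, since its lowest CRL rat was at 33.3%.

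With each library left out, called sites ranged from 0 to 352 for MCW salt, 0 to 323 for CRL salt, 2 to 5157 and 8 to 193 for the colonies on low and high salt, and 6 to 245 for the interaction. They ranged from 0 to 6 for HS_SCR against PRE_LS, 0 to 2 for HS_DT against HS_SCR and 0 to 1 for HS_DT against PRE_LS. Bins ranged from 0 to 135 for the colonies on low salt. Mean methylation differences, none of which passed, ranged from 0.127 to 0.343 for MCW salt, 0.0979 to 0.227 for CRL salt, and -0.0614 to 0.0930 and -0.0460 to 0.170 for the colonies on low and high salt. They ranged from -0.0670 to 0.186 for HS_SCR against PRE_LS, -0.181 to 0.0719 for HS_DT against HS_SCR and -0.0354 to 0.0337 for HS_DT against PRE_LS. Weighted by reads they were 0.739 for MCW salt, 0.850 for CRL salt, -0.309 and -0.421 for the colonies on low and high salt, 1.75 for HS_SCR against PRE_LS, -1.41 for HS_DT against HS_SCR and 0.332 for HS_DT against PRE_LS. On high salt the colony difference was -0.0332 at 20 reads.

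The correlation of salt responses was 0.0331 over bins and 0.0214 at 20 reads, where 5.88% of called sites had the same sign. The share of opposite sign in HS_DT was 6.21% at 20 reads. The salt difference of sites of 20 to 80% ranged from 0.770 to 0.953 with each library left out, and HS_SCR minus PRE_LS in them from -0.292 to 0.365, the latter without HS_SCR replicate 4. Simulated 10 point changes at sites of intermediate level were recovered in 0% of cases for MCW salt and for HS_SCR against PRE_LS. Depth, group size, dispersion and the number of tests were not separated as limits. The gene-list alternatives were not run without an annotation, and no bin was called for the share of opposite or same sign.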

Other observations

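Tests of this part chosen after the result was seen are the spread of the bin differences and the ranges of animal numbers.

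Salt differences in both colonies were weakly correlated over 28130 bins (r = 0.0517). Of 100 splits with diets permuted within colony, the real one included, 4 gave a correlation as high, and the highest other was 0.0621, above the real value. That share counts only correlations as high, not those as low, and is below 0.05 for this test alone, without adjustment for other measures looked at. The lowest other was -0.0736, larger in size than the real value, so counting both directions would raise the share. Bins are not independent replicates.

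A single CpG, at 58903759 of chromosome 16, parted all rats of the colonies by at least 30 points. Of 100 splits only the real one, 1 in all, gave such a site, and the highest other gave 0. In MCW rats of the second experiment it stood at 0 to 1.54% in PRE_LS and 0% in HS_SCR, but at 20.3% and 20% in HS_DT replicates 1 and 2 (64 and 60 reads) and 0% in replicates 3 and 4. Whether the DNA sequence differs there was not tested.

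The SD of bin differences was 4.23 points for MCW salt, 4.13 for CRL salt, 4.17 for the colonies on high salt and 2.93 for HS_DT against PRE_LS. Each of these ranked 1 of 35 splits, with highest others of 4.22, 4.08, 4.07 and 2.90. The rank was 2 for the colonies on low salt (4.28, highest other 4.30), 20 for HS_SCR against PRE_LS (2.93, 3.05) and 30 for HS_DT against HS_SCR (2.90, 3.05). Adjusted over the 7 comparisons the smallest share is 0.05, and the measure was chosen after several others had been looked at, so chance is not excluded. For HS_DT against PRE_LS the rank also cannot separate treatment from the range of animal numbers, which is lower in most HS_DT rats.

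The 5345 sites called with HS_SCR replicates 1 and 2 led to the hypothesis that ranges of animal numbers differ, since those rats and 3 of the 4 HS_DT rats have numbers in a lower range than all PRE_LS rats. Between the ranges within HS_SCR and HS_DT 0 sites passed the limma-moderated model, which makes 24 of 24 splits as large by construction (highest other 5248) and decides nothing. The share of sites at an unadjusted p below 0.05 was 7.69% (40596 of 527815), as high in 1 of 24 splits, the real one, against 7.33% in the highest other, and HS_DT against HS_SCR had 25962 such sites. That share of splits is the smallest 24 can give, for this test alone and without adjustment, so the hypothesis stays open. Median depth at common sites was 73 to 82 reads in the lower range and 88 in the other. Depth and range cannot be told apart in these rats. In the MCW rats of the first experiment 0 sites passed (18 of 18 splits as large, highest other 6084). There 5.36% of sites (8854) had an unadjusted p below 0.05, 8 of 18 splits gave as high a share and the highest other was 9.27%, and these splits are too few for a share under 0.05.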
